A study of Mus musculus with 4 samples.

How the data were processed

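Total RNA from 4 mouse embryonic stem cell lines, 2 UTX conditional knockout (cKO) lines and 2 UTX knockout (KO) lines, was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array each. Per the labels' protocols, the cells were kept on irradiated fibroblast feeders with LIF and serum, moved to gelatin for 2 passages to clear the feeders, and RNA was taken with Trizol and an RNeasy kit. The array carries several short probes per probe set, mostly near the 3' end of a transcript.

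The values the authors deposited are intensity values on a linear scale, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. The version of MAS5 and its settings were not given in the sources used here. The mean signal after trimming 2% from each end was 500 on every array, so each array had been scaled to a common mean, and detection calls were not used here. This scaling fixes the mean of bright probe sets and leaves the median free, which ran from 64.4 to 81.6. Signals near the low end are mostly background, and MAS5 leaves them noisy on a log scale.

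Gene names came from a table of the platform's annotation. Of 45101 probe sets, 64 were controls, 34958 named 1 gene, 932 named several genes and 9160 of the rest named none. Only probe sets naming 1 gene were used, and 34754 of them took a current symbol through an Entrez identifier in a RefSeq gene table (assembly GRCm38.p6), while 204 kept the annotation's own symbol. That table also gave the chromosome of each gene, and no coordinates were used. For each of the 18193 genes the probe set with the highest mean over the 4 arrays stood for the gene. Genes in the lower 40% by mean were left out, which removed 7277 genes below a signal of 77.7 and left 10916. All 4 columns of the value table matched a sample by its accession, and the sample titles gave the group and line number.

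The signals were used as scaled by the authors, with no further normalization. They were converted to log2(signal + 4.79), where 4.79 is the 10th percentile of all values, and every fold change is on this scale, which understates the change of dim genes. KO and cKO were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on signal), with 2 residual degrees of freedom plus 5.13 from the prior, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. As a count without a p-value, genes were listed whose 2 KO values were both at least 2-fold above, or both at least 2-fold below, both cKO values, and the other 2 splits of the arrays were counted in the same way.

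Gene lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, unless stated otherwise. Of 42 lists, 38 had at least 5 tested members and were tested with camera in limma at a preset correlation of 0.01, adjusted over these 38. Camera with an estimated correlation and fry were alternatives. Chromosomes were tested as sets with camera. Genes named are Kdm6a and 9 others chosen beforehand for the design, the 12 called genes of largest increase and the 12 of largest decrease with separated groups, and for each list up to 4 called members of largest change or, where none was called, up to 2 of smallest p. This rule took 106 genes with a named probe set, of which 104 were tested and 50 called, and 2 genes of the rule were not analysed here. Other list members are named as examples chosen after their values were seen. Among called genes 6 were RIKEN clones or predicted genes and are not named. For 15 of the named called genes, 25 further probe sets lay above the filter, and all 25 had the sign of the one used, several with much smaller changes.

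The alternatives were another pseudocount (1, or the 25th percentile), no filter or one on the lower 60%, quantile normalization, centring on the median, the mean of a gene's probe sets, every probe set on its own, eBayes without the trend, the line number as a block, another threshold or fold, and each array left out in turn. Where 1 array was left out, the lone line of its group was assumed to vary like the lines of the other group. Permutation tests, summaries and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

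The procedure was tested on 20 simulated data sets of 10916 genes with 200 genes changed, for the comparison of KO with cKO. It recovered 75.9% of 2-fold changes and 99.3% of 4-fold changes, 7.42% of its calls were unchanged genes, and with no gene changed it made 1.05 calls on average and at most 3. On average 1.7 unchanged genes were 2-fold apart in every pair. A list shifted by 0.5 was called in 20 of 20 sets, with 0.65 other lists called on average. Noise was drawn independently for each gene and array, so correlation within lists and an effect of the line number were absent.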

Results

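Transcript levels were measured in mouse embryonic stem cells, pluripotent cells that grow in culture with leukaemia inhibitory factor (LIF), in lines with and without a working gene for UTX. UTX, encoded by the X-linked gene Kdm6a, is a histone demethylase that acts on trimethylated lysine 27 of histone H3 and belongs to the MLL3/MLL4 histone methyltransferase complexes. The 4 arrays fall into 2 groups of 2 cell lines, a conditional knockout group (cKO lines 1 and 2) and a knockout group (KO lines 1 and 2). The series asks which genes UTX regulates in these cells, so the design holds 1 comparison, KO against cKO. Each array was an Affymetrix Mouse Genome 430 2.0 array with 45101 probe sets, and 2 lines per group limit the precision of every value below. The labels describe the cKO lines as independent but do not say whether the RNA came from separate cultures on separate occasions, so the p-values measure the spread between these 4 samples, part of which may be technical.

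The 4 arrays were alike in RNA quality. The ratio of 3' to 5' control signal lay between 0.795 and 0.838 for Gapdh and between 1.12 and 1.18 for Actb, housekeeping transcripts whose ratio climbs when RNA is degraded. The median signal was 76.6 in cKO line 1, 64.4 in cKO line 2, 81.6 in KO line 1 and 64.9 in KO line 2, and the 18S ribosomal RNA control read 4144, 5583, 4187 and 5465 in the same order. Both measures went with the line number and not with the genotype. Across the 10916 genes tested, Pearson's r of the log2 signals was 0.983 between the cKO lines and 0.981 between the KO lines, against 0.962 to 0.974 for the 4 pairs that join a cKO and a KO line. No pair of arrays shared identical values.

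Kdm6a itself, the targeted gene, was measured first. Its brightest probe set read 658 and 415 in cKO lines 1 and 2 and 265 and 198 in KO lines 1 and 2, or 536 ± 172 against 231 ± 47.4 (mean ± SD, n = 2 each). The log2 fold change was -1.17 (SE 0.27), a level 2.25-fold lower in KO, with both KO values under both cKO values. In limma the unadjusted p was 0.0032 and the adjusted p = 0.0884, which missed the threshold. A second probe set read 382, 267, 153 and 132, so that the KO mean kept 43.9% of the cKO mean, and the other 2 Kdm6a probe sets stayed under 43 on every array, below the filter level of 77.7. The deleted part of the gene and the probe positions were not used here, and a probe set outside the deleted part checks nothing, so these values do not test the labels fully. The call rested on which arrays entered, with -1.50 (adjusted p = 0.0156) without cKO line 2 and -1.38 (adjusted p = 0.00985) without KO line 1, but -0.84 (adjusted p = 0.239) without cKO line 1. Centring each array on its median gave -1.22 (adjusted p = 0.00847). With the line number as a block in limma it was -1.17 (adjusted p = 0.00811), though the labels do not pair the lines. Between lines of the same number the change was -1.30 for number 1 and -1.05 for number 2.

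The relatives of Kdm6a were measured next. Kdm6b, which encodes the related demethylase JMJD3, had a log2 fold change of -0.75 (SE 0.17, adjusted p = 0.0877), with signals of 927 ± 53.1 in cKO and 553 ± 72.2 in KO (SD, n = 2 each). Uty, the Y-linked homologue of Kdm6a, lay below the filter and was not tested, with signals of 57.6 in cKO line 1 and 10.6, 12.2 and 11.5 in cKO line 2, KO line 1 and KO line 2. Eif2s3y, another Y-linked gene below the filter, read 232 in cKO line 1, 48.4 in cKO line 2 and 24.8 in each KO line. Xist, the RNA that coats the inactive X chromosome, had 1 bright probe set at 1192 ± 7.42 in cKO and 1338 ± 313 in KO (log2 fold change 0.15, adjusted p = 0.826), while its other 2 probe sets stayed under 23 on every array.

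Loss of UTX went with more genes lower than higher. Of 10916 genes tested, 240 passed the threshold of adjusted p under 0.05 in limma, 69 higher and 171 lower in KO, and 194 of them differed at least 2-fold (44 higher, 150 lower). The genes that rose most were Msln (mesothelin, a cell surface glycoprotein), Mras (a Ras-family GTPase), Fgf18 (a fibroblast growth factor) and Krt17 (a keratin), each at least 5.01-fold higher by the measured signals, though the cKO mean of Msln lay near background. The genes that fell most by the measured signals were Stmn4 (a stathmin, which acts on microtubules) and Chst15 (a sulfotransferase), whose KO signals were at background so that the size of the fall is uncertain. Next came Nt5e (the ectonucleotidase CD73), Gbp2 (an interferon-induced guanylate-binding protein) and Pkdcc (a secreted kinase).

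Msln went from 71.3 ± 14.9 in cKO to 464 ± 69.6 in KO (SD, n = 2 each), a log2 fold change of 2.63 (SE 0.26, adjusted p = 0.0103). For Mras the log2 fold change was 2.53 (adjusted p = 0.0103), for Fgf18 2.39 (adjusted p = 0.017) and for Krt17 2.32 (adjusted p = 0.0113). The rest of the 12 largest increases were Serpinb6c (2.32), Calml4 (2.13), Fam167a (2.02), Gjb1 (2.01), Stard8 (1.79), Ntn1 (1.70), Mep1b (1.70) and Abca1 (1.69), log2 fold changes with adjusted p between 0.0103 and 0.0399. Ntn1 encodes the guidance factor netrin-1, and Abca1 a cholesterol exporter. With the mean of all probe sets of a gene in place of the brightest, the log2 fold change was 0.92 for Ntn1 (adjusted p = 0.179) and 0.79 for Abca1 (adjusted p = 0.504), and Gjb1 at 2.46 gave an adjusted p = 0.0734, so these 3 calls ended. The cKO means of Msln and of Gjb1 (63.2) lay below the filter level of 77.7, where signal is close to background, so the sizes of these increases are uncertain.

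Stmn4 went from 430 ± 44.4 to 16.8 ± 2.00 and Chst15 from 473 ± 140 to 18.5 ± 0.862 (SD, n = 2 each), log2 fold changes of -4.33 and -4.32 (adjusted p = 0.00441 for both). Both KO levels lay below the filter level of 77.7, where array signal is close to background, as did the KO means of Nt5e, Gbp2, Pkdcc, Gbp2b, Cxcl12, Pcdh1 and Sema3f, so the sizes of these falls are uncertain. The other large decreases were Nt5e (log2 fold change -3.63), Gbp2 (-3.09), Pkdcc (-2.99), Ltb (lymphotoxin beta, -2.69), Gbp2b (-2.54), Plac8 (-2.44), Cxcl12 (a chemokine, -2.35), Cnn1 (calponin 1, -2.32), Pcdh1 (-2.30) and Sema3f (-2.27), with adjusted p from 0.00441 to 0.0483. Gbp2 and Gbp2b are close paralogues whose probe sets may take up each other's transcripts. Plac8 was bright in both groups, 3219 ± 289 in cKO and 590 ± 88.9 in KO (SD, n = 2 each). Calls were lost for Gbp2b (adjusted p = 0.0592), Pcdh1 (adjusted p = 0.146) and Sema3f (adjusted p = 0.1) without cKO line 1, and for Cxcl12 (adjusted p = 0.088) without cKO line 2. With the mean of a gene's probe sets Sema3f was at -1.43 (adjusted p = 0.122), while Chst15 (-2.96), Nt5e (-1.73) and Cxcl12 (-1.36) came to lie below the filter and were not tested.

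**Figure D1:**
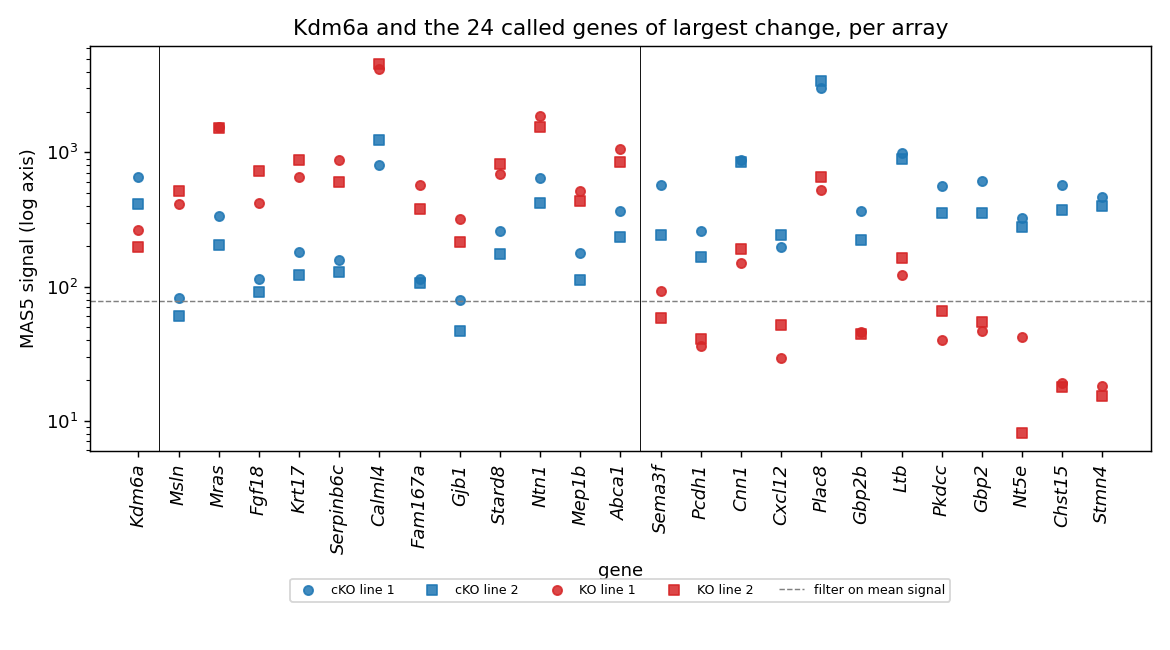
MAS5 signal (log axis) on each of the 4 arrays for Kdm6a, the 12 called genes of largest increase and the 12 of largest decrease in KO, with cKO lines in blue, KO lines in red, circles for line 1 and squares for line 2. For each gene shown both KO values lie on one side of both cKO values, and the dashed line is the filter level of 77.7 on the mean signal.

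The other ways to split the same arrays gave fewer such genes, though each of them puts a KO and a cKO line on both sides. The 2 KO values were at least 2-fold above or below both cKO values for 163 genes, 37 higher and 126 lower. Splitting by line number instead gave 19 such genes, and the crossed split (cKO line 1 and KO line 2 against the rest) gave 1. In limma both other splits called 0 genes, with 1172 genes at an unadjusted p under 0.05 for the line numbers and 16 for the crossed split, against 1509 for KO against cKO, where chance alone gives 545.8. With 3 splits of 4 arrays no permutation test can pass 0.05. The groups did not overlap for 42.6% of genes for KO against cKO and 44.8% for the line numbers, but 12.6% for the crossed split, where chance gives 33.3%.

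The number of calls depended on the model of the variance and on single arrays. Without the trend of variance with signal, 28 genes passed, among them 9 of the 50 named genes called here, namely Stmn4, Chst15, Gbp2, Ltb, Plac8, Cnn1, Sparc, Psmb8 and Msln. Without KO line 1 the count was 432, and 14 of the 50 named genes lost their call without 1 array or another. Of these 50, 17 lost it without a filter, 5 with centring, 2 with quantile normalization, and 18 were no longer called with the mean of a gene's probe sets. The count of genes 2-fold apart was 269 without cKO line 1, 344 without cKO line 2, 302 without KO line 1 and 258 without KO line 2, since fewer pairs must then agree. Centring on the median called 335 genes, 80.6% of them lower in KO, against 71.3% lower with the values as scaled by the authors. Without cKO line 1 the calls were 94 higher and 134 lower (58.8% lower).

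Genes of the naive pluripotent state stood higher as a group in KO cells, and genes of the primed epiblast lower. All 18 naive genes were tested, 16 had a positive log2 fold change, and the median was 0.49 (camera with a preset correlation, adjusted p = 8.19e-07; adjusted p = 0.706 with an estimated correlation). None passed over all genes, and 9 were higher when adjusted over the list alone. The largest values were those of the transcription factors Prdm14 (log2 fold change 1.63, adjusted p = 0.069), Tfcp2l1 (1.24, adjusted p = 0.0889), Esrrb (0.94, adjusted p = 0.115), Nr0b1 (0.91, adjusted p = 0.119) and Klf4 (0.89, adjusted p = 0.13). The naive list also stood apart between the cKO lines, with a median log2 ratio of cKO line 1 to cKO line 2 of 0.53, larger than the median between the groups. Nanog read 5533 and 2969 in the cKO lines and 8237 and 5077 in the KO lines (0.67, adjusted p = 0.427). With 1 array left out its value ran from 0.22 to 1.12. In both groups line 1 read above line 2. Between lines of the same number the change was 0.57 for number 1 and 0.77 for number 2, though the labels do not pair these lines. Prdm14 passed with centring (1.59, adjusted p = 0.00181) and without cKO line 1 (2.12, adjusted p = 0.00217), KO line 1 (1.38, adjusted p = 0.0386) or KO line 2 (1.88, adjusted p = 0.0069), but not without cKO line 2 (1.15, adjusted p = 0.0681). The median of the naive list was 0.30 without cKO line 2.

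Of 12 tested primed epiblast genes, 3 fell, 9 did not pass and 11 had a negative log2 fold change, with a median of -0.69 (adjusted p = 5.96e-06; adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, 5 were lower. The members that fell were Dnmt3a, a de novo DNA methyltransferase (log2 fold change -1.89, SE 0.23, adjusted p = 0.017), and the transcription factors Sox3 (-1.34, adjusted p = 0.0347) and Sox4 (-1.13, adjusted p = 0.0256). Signals of Dnmt3a were 4060 ± 991 in cKO and 1096 ± 281 in KO (SD, n = 2 each), and its other 4 probe sets above the filter went the same way. Sox3 missed the threshold without cKO line 1 (-1.22, adjusted p = 0.102), and with the mean of all probe sets Sox3 gave -1.44 (adjusted p = 0.2) and Sox4 -0.28 (adjusted p = 0.762).

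The core pluripotency list did not pass as a group (median log2 fold change -0.01, adjusted p = 0.52). Pou5f1, the gene for OCT4, read 10814 ± 650 in cKO and 10342 ± 230 in KO (SD, n = 2 each; log2 fold change -0.06, adjusted p = 0.847), and Sox2 had a log2 fold change of 0.37 (adjusted p = 0.0994). Among its 13 tested genes 2 fell, Dnmt3l, a cofactor of DNA methyltransferases (-1.50, adjusted p = 0.0178), and Lin28a, an RNA-binding protein (-0.66, adjusted p = 0.0346), and 3 passed when adjusted over the list alone. Lin28a lost its call without cKO line 1 (-0.71, adjusted p = 0.06) and without cKO line 2 (-0.62, adjusted p = 0.115). It lost it also with centring (adjusted p = 0.312) and with the mean of its probe sets (-0.46, adjusted p = 0.231). The 13 DNA methylation genes, which include Dnmt3a and Dnmt3l as their only 2 called members, gave an adjusted p = 0.52, and 5 passed when adjusted over the list alone.

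LIF and STAT3 targets were higher as a group, with 13 of 15 tested members positive and a median log2 fold change of 0.22 (adjusted p = 2.17e-05; adjusted p = 0.706 with an estimated correlation). The 2 that rose were Socs3, the feedback inhibitor of this pathway, from 2333 ± 172 to 5141 ± 273 (SD, n = 2 each; 1.14, SE 0.13, adjusted p = 0.0116), and Lifr, the LIF receptor (1.05, SE 0.15, adjusted p = 0.0209). The call of Lifr ended with centring (1.01, adjusted p = 0.0593), with the mean of its probe sets (0.75, adjusted p = 0.162) and without the variance trend (adjusted p = 0.0715), and the last also ended that of Socs3 (adjusted p = 0.0628). Adjusted over the list alone, 6 were higher. Klf4, Gbx2, Klf5 and Tfcp2l1 are on this list and on the naive list. The median was 0.34 without KO line 2.

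**Figure D2:**
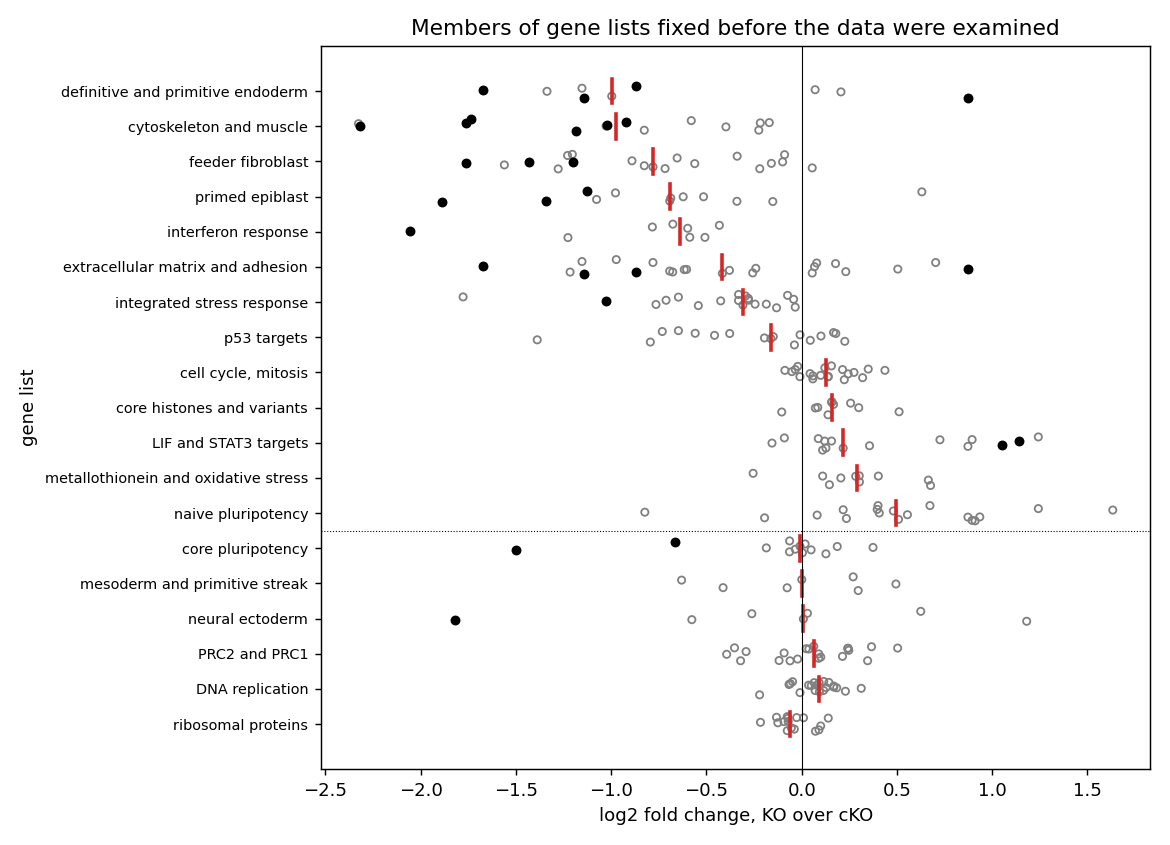
Log2 fold change (KO over cKO) of each tested member of the 13 gene lists past the camera threshold with a preset correlation, above the dotted line, and of 6 lists that did not pass, below it; filled points passed the threshold over all genes, open points did not, and red bars are list medians. The cytoskeleton and muscle list has every point below 0, and the naive pluripotency list has 16 of 18 above 0.

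Genes of the actin cytoskeleton and smooth muscle were lower as a group in KO cells with camera's preset correlation. Of 14 tested members 6 fell, 8 did not pass and all 14 had a negative log2 fold change, with a median of -0.97 (camera with a preset correlation, adjusted p = 3.7e-12; adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, 10 were lower. The members that fell were Cnn1 (log2 fold change -2.32, SE 0.19, adjusted p = 0.00548), Tagln (transgelin, -1.76, adjusted p = 0.0056), Acta1 (-1.74, adjusted p = 0.0349), Myl9 (a myosin light chain, -1.19, adjusted p = 0.0256), Tpm1 (-1.02, adjusted p = 0.0304) and Tpm2 (-0.92, adjusted p = 0.0324). Tagln went from 8015 ± 1306 to 2350 ± 169 (SD, n = 2 each). The keratin genes Krt8 (-1.81, adjusted p = 0.0113) and Krt18 (-1.57, adjusted p = 0.0192), on the trophectoderm list, fell as well.

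Markers of fibroblasts, the feeder cells on which these lines were kept before passage on gelatin, were lower as a group too. Of 19 tested feeder fibroblast genes 3 fell, Tagln, Col5a1 (log2 fold change -1.43, adjusted p = 0.0295) and Thy1 (-1.20, adjusted p = 0.0483), and 18 were negative, with a median of -0.78 (adjusted p = 7.31e-08; adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, 11 were lower. Tagln and Acta2 are on both this list and the cytoskeleton list, and without these 2 genes the medians were -0.97 for the cytoskeleton list and -0.72 for the feeder list, an alternative chosen after the data were seen. The fibroblast collagens stood higher in cKO line 1 than in cKO line 2. Col1a1 read 618, 246, 146 and 171 and Col3a1 read 299, 145, 67.8 and 67.0 in cKO lines 1 and 2 and KO lines 1 and 2, an order that Eif2s3y, at 232, 48.4, 24.8 and 24.8, shared between the cKO lines. The feeder median was -0.45 without cKO line 1. Col5a1 missed the threshold without cKO line 1 (-1.22, adjusted p = 0.0938), and Thy1 without cKO line 2 (-1.04, adjusted p = 0.163) and without KO line 2 (-1.03, adjusted p = 0.0574). Both missed it with the mean of probe sets (adjusted p = 0.0563 and 0.0566).

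**Figure D3:**
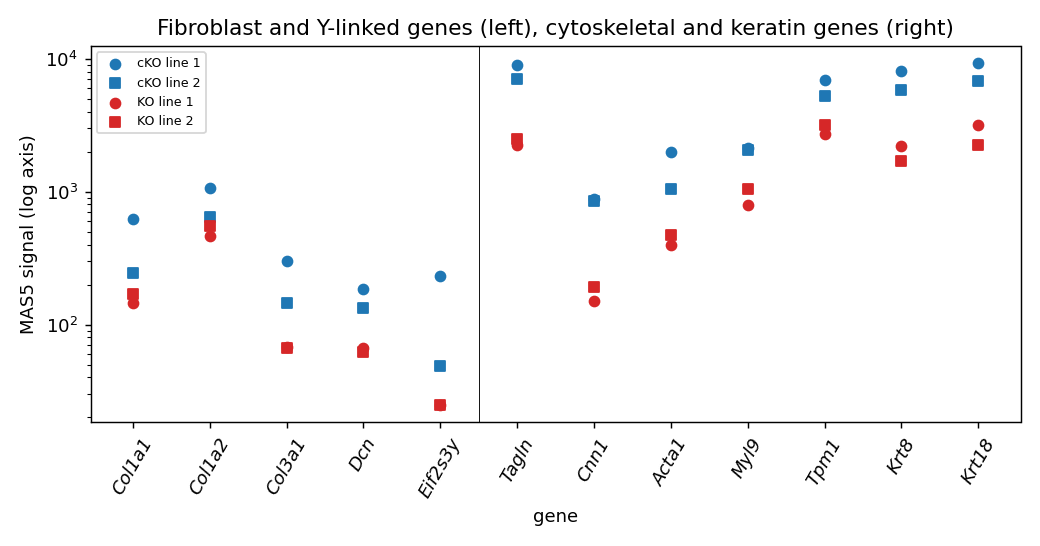
MAS5 signal (log axis) on each array of fibroblast genes and the Y-linked Eif2s3y (left) and of cytoskeletal and keratin genes (right), with cKO lines in blue, KO lines in red, circles for line 1 and squares for line 2. Col1a1 reads 618 in cKO line 1 and 246 in cKO line 2, while Cnn1 reads 885 and 847 in the same lines.

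Extracellular matrix and adhesion genes were lower as a group, with a median log2 fold change of -0.42 over 23 tested genes (adjusted p = 0.00114; adjusted p = 0.706 with an estimated correlation). The matrix protein gene Sparc fell from 7639 ± 165 to 2396 ± 116 (SD, n = 2 each; -1.67, SE 0.12, adjusted p = 0.00441), Col4a1 (a basement membrane collagen, -1.15, adjusted p = 0.0483) and Lamb1 (a laminin chain, -0.87, adjusted p = 0.0483) fell, and Lama1, another laminin chain, rose (0.87, adjusted p = 0.043). Adjusted over the list alone, 10 passed, 8 lower and 2 higher. The same 4 genes were the called members of the definitive and primitive endoderm list (9 tested, median -0.997, adjusted p = 0.00174; adjusted p = 0.706 with an estimated correlation; 7 passed when adjusted over the list alone). These 4 are components or binding partners of basement membrane. Of the other members, Dab2 (-1.34, adjusted p = 0.0576) and Amn (-0.997, adjusted p = 0.133) were lower when adjusted over the list alone. Cubn, below the filter and not tested, read 241 in cKO and 34.1 in KO on average. The filter acts on the mean of log2 values, so lines within a group must have differed widely. These averages therefore do not show a fall between every pair of lines. The endoderm transcription factors Gata4, Gata6, Sox17 and Sox7 lay below the filter and were not tested. Without cKO line 1, Col4a1 (-0.85, adjusted p = 0.0911), Lamb1 (-0.77, adjusted p = 0.128) and Lama1 (0.89, adjusted p = 0.0791) missed the threshold. Lama1 also missed it without cKO line 2 (adjusted p = 0.105) and without KO line 2 (adjusted p = 0.104), and Lamb1 without KO line 1 (adjusted p = 0.0823). With centring Lama1 (adjusted p = 0.134) and Lamb1 (adjusted p = 0.106) lost their calls. The mean of probe sets ended those of Col4a1 (adjusted p = 0.15), Lamb1 (adjusted p = 0.197) and Lama1 (adjusted p = 0.0513). The fibroblast collagens Col1a1 and Col3a1 given above moved the same way between groups as this list.

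Interferon response genes were lower as a group, with all 8 tested members negative and a median log2 fold change of -0.64 (adjusted p = 5.96e-06; adjusted p = 0.706 with an estimated correlation). The 1 member that fell was Psmb8, an immunoproteasome subunit, from 204 ± 11.5 to 45.6 ± 9.40 (SD, n = 2 each; -2.06, SE 0.31, adjusted p = 0.0258), and 6 were lower when adjusted over the list alone. Psmb8 missed the threshold without cKO line 1 (adjusted p = 0.0772) and without cKO line 2 (adjusted p = 0.0952), and the mean of its probe sets (-1.38) lay below the filter. Its KO mean lay below the filter level of 77.7, so the size of this fall is uncertain. The feeder fibroblast list (median -0.78) was lower as well. Classical interferon-induced genes such as Ifit1, Mx1 and Rsad2 lay below the filter and were not tested. The guanylate-binding protein genes Gbp2 and Gbp2b, which are not on this list, are the interferon-inducible genes named above among the largest decreases.

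Integrated stress response genes were lower by a small amount, with all 19 tested members negative and a median log2 fold change of -0.31 (adjusted p = 1.86e-06; adjusted p = 0.706 with an estimated correlation). Cth, an enzyme of cysteine synthesis, was the 1 member that fell, from 4382 ± 471 to 2148 ± 241 (SD, n = 2 each; -1.03, adjusted p = 0.0228), and 3 were lower when adjusted over the list alone. The call of Cth ended with centring (adjusted p = 0.0561) and without the variance trend (adjusted p = 0.0793). Atf3 had a log2 fold change of -1.78 (adjusted p = 0.0963), while Atf4 and Ddit3 were at -0.07 and -0.03. The median was -0.20 without cKO line 2 and -0.47 without cKO line 1. The list's median log2 ratio of cKO line 1 to cKO line 2 was -0.26, close in size to the change between the groups. Its members varied together, with an estimated correlation of 0.34, so their shared sign is not independent agreement.

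The other 4 lists past the threshold had no called member. Of 17 p53 targets the median log2 fold change was -0.16 (adjusted p = 0.0105; adjusted p = 0.734 with an estimated correlation), with Plk2 at -1.39 (adjusted p = 0.0841; past the threshold with centring, at 0.00434, and without cKO line 2, at 0.00418, or KO line 1, at 0.00162, but at -0.98 without cKO line 1), and 4 were lower when adjusted over the list alone; the list's median log2 ratio of cKO line 1 to cKO line 2, 0.26, was larger than that between the groups. Metallothionein and oxidative stress genes had a median of 0.29 over 10 genes (adjusted p = 0.00149; adjusted p = 0.706 with an estimated correlation), with Nqo1 at 0.68 (adjusted p = 0.112), and 2 were higher when adjusted over the list alone. Mitotic cell cycle genes had a median of 0.13 over 20 genes (adjusted p = 0.0163; adjusted p = 0.734 with an estimated correlation), with Ccnb2 at 0.44 (adjusted p = 0.131), and core histones and variants 0.16 over 10 genes (adjusted p = 0.0485; adjusted p = 0.706 with an estimated correlation), with Macroh2a1 at 0.51 (adjusted p = 0.135). In neither of the last 2 lists did any member pass when adjusted over the list alone. Without cKO line 1 the p53 (-0.10, adjusted p = 0.278), cell cycle (0.06, adjusted p = 0.476) and histone (0.11, adjusted p = 0.166) lists missed the threshold. Without KO line 2 they missed it too, at -0.11 (adjusted p = 0.156), 0.05 (adjusted p = 0.416) and 0.09 (adjusted p = 0.455), and the histone list also without cKO line 2 (0.22, adjusted p = 0.0734).

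In all, 13 of the 38 lists tested passed with camera's preset correlation of 0.01, 5 higher and 8 lower in KO. With a correlation estimated from these 4 arrays 0 lists passed, and 1 had an unadjusted p under 0.05. In simulated data of this design a list shifted by 0.5 on the log2 scale was called in 20 of 20 sets with the preset correlation and in 0 of 20 with the estimated one. Noise was drawn there independently for each gene and array. The simulation therefore cannot show how the preset correlation acts on lists whose members vary together, such as the naive list with an estimated correlation of 0.33. The rotation test fry called 0 lists for a shift in 1 direction (smallest adjusted p = 0.116, 9 lists at an unadjusted p under 0.05) and 20 lists for change in either direction.

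The chromatin complexes around UTX did not pass as groups. The 10 genes of the MLL3/MLL4 complexes had a median log2 fold change of 0.03 (adjusted p = 0.933), and apart from Kdm6a the largest was Ash2l at 0.27 (adjusted p = 0.309). Polycomb genes (21 tested, median 0.06, adjusted p = 0.524), JmjC demethylases (20 tested, median -0.09, adjusted p = 0.379) and genes of X inactivation, escape and sex (7 tested, median -0.06, adjusted p = 0.597) did not pass either. Kdm6a and Kdm6b had the smallest p among the JmjC demethylases, with the values given above.

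Lineage lists other than endoderm did not pass as groups with all 4 arrays as scaled, though single members did. Of 7 neural genes Nes, the gene of the intermediate filament nestin, fell from 897 ± 130 to 262 ± 115 (SD, n = 2 each; log2 fold change -1.82, adjusted p = 0.0325; -0.78 and adjusted p = 0.443 with the mean of its probe sets), and the list gave an adjusted p = 0.687. Of 13 trophectoderm genes Krt8, Krt18 and Cited1 (-1.45, adjusted p = 0.0372) fell (list adjusted p = 0.183), and Cited1 missed the threshold without cKO line 1 (adjusted p = 0.156) and without cKO line 2 (adjusted p = 0.0546). Mesoderm and primitive streak genes, of which 7 were tested, had a median of 0.00069 (adjusted p = 0.597), with Fgf17 at 0.49 (adjusted p = 0.178) and Eomes at -0.63 (adjusted p = 0.606; from -1.20 to -0.056 with 1 array left out). Heart and vessel genes (9 tested, median -0.45, adjusted p = 0.127) included Actc1 at -2.33 (adjusted p = 0.0769), and germ cell genes (11 tested, median 0.37, adjusted p = 0.317; 0.095 without KO line 1) included Prdm1 at 1.26 (adjusted p = 0.103). The heart and vessel list passed with centring (-0.49, adjusted p = 0.00928), without cKO line 2 (-0.48, adjusted p = 0.031) and without KO line 1 (-0.84, adjusted p = 0.00374), but not without cKO line 1 (-0.34, adjusted p = 0.328) or KO line 2 (-0.05, adjusted p = 0.43). So did the trophectoderm list with centring (-0.26, adjusted p = 0.038), without cKO line 2 (-0.39, adjusted p = 0.00299) and without KO line 1 (-0.42, adjusted p = 0.016), while it stood at 0.016 without cKO line 1. Actc1 passed with centring (adjusted p = 0.000478) and without cKO line 2 (-3.11), KO line 1 (-2.64) or KO line 2 (-2.01), but not without cKO line 1 (-1.54, adjusted p = 0.201). Its KO mean of 62.7 lay below the filter level. Prdm1 passed with centring (1.21) and without cKO line 1 (1.65) or KO line 2 (1.48), but not without cKO line 2 (0.87, adjusted p = 0.22) or KO line 1 (1.04, adjusted p = 0.125).

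Among 21 imprinted genes 2 fell, the growth-restricting genes Phlda2, from 7272 ± 564 to 2873 ± 125 (SD, n = 2 each; log2 fold change -1.34, SE 0.12, adjusted p = 0.00816), and Cdkn1c (-1.05, adjusted p = 0.0278; -0.93 and adjusted p = 0.0693 without cKO line 2). The imprinted list did not pass as a group (adjusted p = 0.266). The Wnt target Notum, which encodes a secreted Wnt inhibitor, rose from 556 ± 97.2 to 1653 ± 274 (SD, n = 2 each; 1.56, adjusted p = 0.0174), while the 11 Wnt targets tested had a median of -0.25 (adjusted p = 0.597; from -0.20 to -0.074 with 1 array left out). The retinoic acid target Crabp2 fell (-1.53, adjusted p = 0.0191) among 5 tested (list adjusted p = 0.498). Nodal and Activin targets (adjusted p = 0.173), BMP targets (adjusted p = 0.375) and FGF and ERK targets (adjusted p = 0.147) had no called member. FGF and ERK targets, at a median of -0.27, passed as a group with centring (-0.32, adjusted p = 0.0237), with the mean of probe sets (-0.32, adjusted p = 0.0411), without cKO line 2 (-0.30, adjusted p = 0.000297) and without KO line 1 (-0.36, adjusted p = 0.000285), but stood at 0.067 without KO line 2. BMP targets, at 0.24, passed without cKO line 1 (0.39, adjusted p = 0.00747) and without KO line 2 (0.40, adjusted p = 0.0403), but stood at 0.0077 without cKO line 2 and 0.031 without KO line 1. Lefty1 and Lefty2, feedback inhibitors of Nodal, had log2 fold changes of -0.54 and -0.60 (adjusted p = 0.0953 and 0.118), and Lefty1 passed without cKO line 2 (-0.68, adjusted p = 0.0376) but was at -0.39 without cKO line 1.

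Metabolic and housekeeping lists had no called member and did not pass with all 4 arrays. Their medians ran from -0.06 for ribosomal proteins (adjusted p = 0.537) to 0.09 for DNA replication (adjusted p = 0.194). Between these lay apoptosis (-0.04, adjusted p = 0.597), heat shock (-0.02, adjusted p = 0.407), cholesterol synthesis (-0.01, adjusted p = 0.709), hypoxia and glycolysis (-0.01, adjusted p = 0.88), endoplasmic reticulum chaperones (0.01, adjusted p = 0.537) and oxidative phosphorylation (0.05, adjusted p = 0.52). Cholesterol synthesis passed without KO line 1 (-0.22, adjusted p = 0.0462) and stood at 0.11 without KO line 2. Hox genes, the 2-cell-like state, globins and erythroid genes, and the placental prolactin and Rhox cluster had fewer than 5 members above the filter and were not tested as groups; of their members Rhox6 was at 0.81 (adjusted p = 0.0732) and Rhox9 at 0.77 (adjusted p = 0.126), both past the threshold without KO line 1 (adjusted p = 0.026 and 0.024) and at their lowest, 0.65 and 0.55, without KO line 2.

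No chromosome stood apart as a whole. Of 20 chromosomes tested as gene sets with camera, 0 passed and 0 had an unadjusted p under 0.05, the smallest being 0.208, and camera with an estimated correlation also called 0. Median log2 fold changes per chromosome ran from -0.01 to 0.06. Each array's chromosome medians lay within -0.03 and 0.03 of the median of the 4 arrays, where an extra copy of a chromosome in every cell would shift it by up to 0.58.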

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

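The direction of every named gene called and of all 13 lists called held under every alternative run. Many of these could not have changed it. The groups of the called genes did not overlap, so leaving out an array cannot turn their sign. The filter, the variance trend and the block leave a gene's fold change as it was. The estimated correlation and fry leave the list medians as they were. The 2 alternatives that take genes shared between the feeder and cytoskeleton lists out of either were chosen after the data were seen, and neither list lost its call. Signal over background limits the dim genes, which is where the filter acts.

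The count of 240 genes past the threshold became 147 without a filter (18193 genes tested), 154 with the lower 60% left out (7277 tested), 129 with the mean of a gene's probe sets, 28 without the variance trend and 428 at an adjusted p under 0.1, and ran from 228 to 432 with 1 array left out. Quantile normalization called 241 genes, 217 of them among the 240, and centring called 335, 189 of them among the 240. The 163 genes 2-fold apart became 314 without a filter, 71 with the lower 60% left out, 303 over single probe sets and 498 at 1.5-fold, and ran from 258 to 344 with 1 array left out, where fewer pairs must differ. The 13 called lists became 0 with an estimated correlation and 0 with fry. Chromosomes gave 0 throughout. Apart from a stricter filter, which tests fewer genes, and left-out arrays, the cause of these shifts was not tested.

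Kdm6a, at -1.17 and short of the threshold, passed it with centring (-1.22) and ran from -0.84 to -1.50 with 1 array left out, passing without cKO line 2 and without KO line 1; the adjusted p over its alternatives ran from 0.00811 to 0.522. It gave no value with the lower 60% left out. The cause was not tested.

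With the line number as a block, 1048 genes passed (431 higher, 617 lower), among them all 240, and Kdm6a passed at -1.17 (adjusted p = 0.00811). Samples of the same number deviated together (correlation 0.52). Their median signals were close too, at 76.6 and 81.6 for cKO line 1 and KO line 1, and 64.4 and 64.9 for cKO line 2 and KO line 2. The arrays thus differed by line number, and the main fit leaves this difference in its residual. The labels do not say that a KO line came from the cKO line of its number, so the source of the difference is not known. The block ended no call of a named gene or list and added 30 named genes, Nanog and Prdm14 among them, and 1 list, FGF and ERK targets (adjusted p = 0.0257).

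Among tested genes and lists, 7 gene values and 38 list medians changed sign, counted over settings, none called. Median log2 fold changes of hypoxia and glycolysis became 0.0097 without a filter, 0.042 with the lower 60% left out and 0.0081 with quantile normalization; X inactivation 0.0080 with the lower 60% left out; and neural genes -0.044 with quantile normalization. Centring gave -0.039 for neural genes, -0.035 for endoplasmic reticulum chaperones, -0.047 for mesoderm and -0.015 for the MLL3/MLL4 complexes. The mean of probe sets gave -0.25 for Hoxa5, 0.083 for Idi1 and for cholesterol synthesis, 0.018 for core pluripotency, 0.061 for DNA methylation, -0.063 for endoplasmic reticulum chaperones, 0.0058 for heat shock, 0.012 for JmjC demethylases, 0.015 for ribosomal proteins and 0.012 for X inactivation. With 1 array left out the ranges were -0.12 to 0.037 for apoptosis, -0.064 to 0.081 for endoplasmic reticulum chaperones, -0.078 to 0.039 for JmjC demethylases, -0.018 to 0.098 for oxidative phosphorylation, -0.42 to 0.016 for trophectoderm, -0.091 to 0.035 for DNA methylation, -0.061 to 0.023 for hypoxia and glycolysis, -0.20 to 0.37 for mesoderm, -0.31 to 0.24 for neural genes, -0.22 to 0.11 for cholesterol synthesis, -0.048 to 0.0098 for core pluripotency, -0.36 to 0.067 for FGF and ERK targets and -0.13 to 0.014 for ribosomal proteins. For genes they were -0.34 to 0.49 for Hoxa5, -0.55 to 0.046 for Msmo1, -0.29 to 0.057 for Klf1 and -0.093 to 0.39 for Xist. Uty, below the filter and so not counted, ran from -1.91 to 0.11. The cause was not tested.

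Of the 50 named genes called, 17 lost the call without a filter, 41 without the variance trend and 14 with the mean of probe sets, where 4 more (Chst15, Nt5e, Cxcl12 and Psmb8) came under the filter, so that 18 were no longer called. With the lower 60% left out, 23 came under the filter and had no test. With 1 array left out, 11 lost it without cKO line 1, 7 without cKO line 2, 1 without KO line 1 and 2 without KO line 2.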

Other observations

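The tests and gene groups in this part were chosen after the results were seen, except that the feeder, cytoskeleton, naive and core lists were fixed before.

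Some antigen presentation genes and annexins, picked for description because members had been seen among the called genes, fell in KO. No group test is given for them, since the choice fixes its outcome. Of 13 tested genes of MHC class I presentation 4 fell, H2-K1 (log2 fold change -1.12, SE 0.17, adjusted p = 0.0256), H2-D1 (-0.93, adjusted p = 0.0324), the peptide-loading chaperone gene Tapbp (-1.13, adjusted p = 0.0367) and Psmb8 (-2.06, adjusted p = 0.0258, with a KO mean below the filter level), and 9 did not pass. H2-K1 and H2-D1 are close paralogues, and whether their probe sets take up each other's transcripts was not tested. Of 7 tested annexins, calcium-dependent membrane-binding proteins, 4 fell, Anxa1 (-1.25, adjusted p = 0.045), Anxa2 (-1.46, adjusted p = 0.0146), Anxa3 (-1.64, adjusted p = 0.017) and Anxa5 (-1.70, adjusted p = 0.0197), and 3 did not pass. The annexins stood higher in cKO line 1 than in cKO line 2 by a median of 0.38 on the log2 scale, as the feeder fibroblast genes did by 0.47, while the antigen presentation genes differed by -0.11.

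Of 9 tested genes of the Hedgehog pathway, also picked after the results were seen, 2 rose, 0 fell and 7 did not pass. Gli1, a transcription factor and target of the pathway, rose from 706 ± 65.8 to 1882 ± 46.4 (SD, n = 2 each; log2 fold change 1.41, SE 0.15, adjusted p = 0.0113), and Ptch1, the receptor and also a target, rose (1.12, SE 0.17, adjusted p = 0.0258). Gli2 was at 0.72 (adjusted p = 0.131), Gli3 at -1.03 (adjusted p = 0.0764) and the signal transducer Smo at -0.78 (adjusted p = 0.0687). The ligand gene Shh read 101.1 ± 5.92 and 126.5 ± 44.5 in cKO and KO (SD, n = 2 each).

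The lower cytoskeleton genes in KO might come from more feeder fibroblasts left in the cKO cultures, since the fibroblast collagens were highest in cKO line 1; Eif2s3y was too, but whether its signal came from feeders or from the line itself is not settled by these arrays. One source of RNA keeps its genes in a fixed ratio, and the median log2 ratio of cKO line 1 to cKO line 2 was 0.72 for 7 collagens and 0.18 for 12 cytoskeleton genes not on the feeder list, a difference of 0.549 (exact two-sided permutation p = 0.0286 over genes, which are not independent). With the KO mean taken off as a baseline, the share of the excess of both cKO lines held by cKO line 2 was compared. Its median was 19.9% for the collagens and 39.4% for the cytoskeleton genes (exact two-sided permutation p = 0.0204). The shares ran from -21.6% to 38.6% for the collagens, of which only 5 of 7 read above the KO mean in cKO line 2. For the cytoskeleton genes they ran from 16.8% to 55.6%, and 6 of the 12 lay within the collagens' range. The medians argue against feeder cells as the whole cause. Each ratio rests on 1 array per line, and a negative value is not a true share, so a part in the fall of these genes stays open. Scaling of the arrays by a common factor is argued against, because it would move all genes alike, and the median log2 fold change of all tested genes was 0.0081. The median of the cytoskeleton list was no nearer to 0 than -0.976 under quantile normalization and centring. Centring moves every gene by the same small amount, so it could not have brought this list near 0. A lower actin and smooth muscle programme in cells without UTX stays an open hypothesis beside feeder cells and differences between clonal lines.

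Higher naive and lower primed genes in KO could reflect a larger share of differentiated cells in the cKO cultures. Cells without pluripotency genes would lower all of them in cKO alike. The naive list (median log2 fold change 0.49) exceeded the core list (median -0.01) by 0.504 (two-sided permutation p = 0.0024 over genes, which are not independent, 100000 draws). This argues against such cells as the whole cause for the naive genes. For the primed genes such cells cannot be told apart from a change in the stem cells. The endoderm list (median -0.997) and Krt8 and Krt18 stood higher in cKO as well. So did the heart and vessel (-0.45) and trophectoderm (-0.21) medians, of lists that did not pass. The mesoderm (0.00069) and neural (0.0091) medians did not, but they rest on 7 tested genes each and changed sign with 1 array left out. Primed cells that keep the core genes were not tested. A shift of the KO lines towards the naive state, with Socs3 higher and Dnmt3a and Dnmt3l lower, is a hypothesis found and tested on the same data, and the naive list differed by a median of 0.53 between the cKO lines as well. Differences in passage number or subclone between the lines were not tested, and with 2 lines per group they go with the genotype.

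The Kdm6a signal that stayed in the KO lines could come from unrecombined cells mixed into the KO cultures. At the 43.9% of the cKO signal kept by the second probe set (43.8505 before rounding), such a mixture would hold every other gene at or above the share that Kdm6a keeps, which was 30.1% in the lowest KO and cKO pair. Of 10749 genes with a KO mean above the filter level 33 lay below this by fold change, 6 at an unadjusted one-sided p under 0.05 and 0 at an adjusted p under 0.05. Among the largest falls, Plac8 kept 18.3% of its cKO mean. Stmn4 and Chst15 kept 3.9% each, but the test left out genes with KO means under the filter level, so it could not count these falls. Both KO values were at least 4-fold below both cKO values for 11 genes, and as far above for 3. Each other split of the arrays gave 0 genes in either direction. Such falls lie below the share that the mixture allows in every pair. They argue against unrecombined cells as the whole source, if such cells express these genes as the cKO lines do. This count was read after the results were seen, and it includes genes with KO signals near background. Whether the probe sets lie outside the deleted part cannot be told, because neither the deleted exons nor the probe positions were used here.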
